A study of Mus musculus with 20 samples.

How the data were processed

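Total RNA of mouse frontal cortex and hippocampus was sequenced in 20 libraries, 5 per genotype and region, after extraction with the RNeasy Mini kit, per the labels' protocols. The groups and replicate numbers were taken from the sample titles. The deposited values are expected counts per gene in 1 table per region, not scaled for depth. Between 22.6% and 27.3% of the values of a library were more than 0.001 away from a whole number, which is how the unit was read from the values. STAR 2.7.3a and Partek are named as processing tools and mm10 as the build, per the labels. The annotation, the strand setting and any filter are not given in the sources used here. The lowest total of a listed gene over the 10 libraries of a table was 10, and 0 genes of the mitochondrial genome were listed. For cortex 17442 genes were listed and for hippocampus 17586, of which 17148 were shared. Gene symbols were compared with a RefSeq table of assembly GRCm38.p6, where 99.6% of the symbols were found and 47.1% of these had the same start and end. Coordinates are therefore those of the deposited tables, counted from 1.

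Depth ranged from 16.6 M to 34.6 M counts per library. The 45S pre-ribosomal RNA, Rn45s, took 0.661% to 4.00% of the counts of a library. Library pairs within a group were checked for duplicates with a chi-square of their counts over genes with at least 20 counts, and the lowest value per degree of freedom was 3.45, so no pair was treated as 1 library. Xist was at most 0.456 CPM and Ddx3y at least 67.7 CPM in each library.

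Expected counts were rounded and fitted in edgeR 4.0.16 under R 4.3.3, with genes kept by filterByExpr, TMM scaling, and quasi-likelihood tests with Benjamini-Hochberg adjustment at 0.05. The filter kept 14823 genes in cortex and 15042 in hippocampus, with 99.945% of the counts in cortex and 99.955% in hippocampus. Genotypes were compared within each region, regions within each genotype, and the interaction of genotype and region over the 20 libraries. Standard errors of log2 fold changes were derived from the fold change and the F statistic. Log2 levels per library used a prior count of 2. Ncs1 was also tested with an exact permutation test of log2 levels. Calls within 10 Mb of Ncs1 were set against calls elsewhere with Fisher's exact test.

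The design, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. The rule named Ncs1, up to 12 genes per direction with the smallest adjusted p, list members that passed, up to 4 members with the smallest p in lists that passed (of which the first is given), and the 10 genes with the smallest p where fewer than 5 besides Ncs1 passed. For regions it named the 8 largest fold changes per direction among genes with a mean of at least 10 CPM and no overlap between groups, of which 1 is not reported here. Coq4 and Serpina3g were named after their values were seen. There were 36 lists, of which 1 had no tested member, and lists with at least 3 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation, and with fry. In each library the median of a list was also computed and compared by exact permutation.

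Alternatives were other scaling factors, DESeq2 1.42.0, limma-voom, other filters, the replicate number as a block, each library left out in turn, haemoglobin genes removed, all libraries in 1 fit, genes near Ncs1 removed, the first surrogate variable from sva 3.50.0, and glmTreat against folds of 1.2 and 1.5. Alternatives chosen after the data were seen were removal of the trend of each library with exonic length (lowess, span 0.3), removal of Rn45s, leaving out 3 hippocampus libraries with the most Ttr, and a fit that took genotype and number as 1 mouse. Exonic length came from the GENCODE annotation by symbol and was found for 98.2% of the tested genes of each region.

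The methods were tested on simulated counts with 50 genes changed at each of 4 folds. For the cortex comparison, over 14714 simulated genes, edgeR recovered 17 of 50 genes changed 1.2-fold, 34 at 1.5-fold, 45 at 2-fold and 50 at 3-fold, and 6 of 152 calls were genes left unchanged. DESeq2 called 180 genes in the same data, 23 of them unchanged. In simulated lists moved 1.15-fold in cortex, camera with either correlation and fry recovered 5 of 5 and called 0 of 22 untouched lists. The simulated genes varied independently of each other. These list counts therefore do not tell how the list tests behave where genes vary together. Nor do the gene counts give the power of the real cortex fit. With 152 calls the adjusted threshold was looser than with the 4 calls of the real data.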

Results

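RNA from frontal cortex and hippocampus was sequenced in mice with both copies of Ncs1 intact and in Ncs1-/- mice, all on the C57Bl6/J background. Ncs1 encodes neuronal calcium sensor 1, a calcium-binding protein of neurons. The 20 libraries formed 4 groups of 5, wild-type cortex, knockout cortex, wild-type hippocampus and knockout hippocampus. Total counts per library ranged from 16.6 M to 34.6 M, with a median of 21.0 M. Knockout hippocampus libraries were the deepest, at 28.5 ± 5.19 M (SD, n = 5), and knockout cortex libraries the shallowest, at 18.5 ± 1.43 M (SD, n = 5). No label says that libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical in part. Levels are in CPM after TMM scaling.

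The level of the targeted gene was compared first, since it checks the genotype labels. In cortex, Ncs1 was at 365 ± 17.5 CPM in wild type and 257 ± 3.88 CPM in knockout (SD, n = 5 each), so knockout libraries kept 70.5% of the wild-type level. In hippocampus the levels were 442 ± 16.2 and 303 ± 19.6 CPM (SD, n = 5 each), and 68.5% was kept. Every knockout library lay below every wild-type library of its region, with cortex ranges of 254 to 264 against 348 to 385 CPM and hippocampus ranges of 282 to 328 against 430 to 470 CPM. The exact permutation test of the 252 arrangements gave a two-sided p of 0.00794 in each region, the smallest it can give. Counts per gene do not separate exons, so the remaining reads could not be assigned to a part of the transcript.

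The first question was which genes differ between genotypes in frontal cortex. Of the genes that passed, Hmcn2 rose most, from 0.514 ± 0.194 CPM in wild type to 4.42 ± 0.844 CPM in knockout (SD, n = 5 each). It encodes hemicentin 2, a large extracellular matrix protein, and its log2 fold change was 3.11 (SE 0.23), an 8.64-fold difference. Trub2, which encodes a pseudouridine synthase of mitochondrial RNA, rose from 24.2 ± 2.17 to 35.3 ± 1.34 CPM (SD, n = 5 each), a log2 fold change of 0.54 (SE 0.06). Lypd6b, which encodes a membrane-anchored modulator of nicotinic acetylcholine receptors, fell by 1.05 on the log2 scale (SE 0.13), from 13.5 ± 1.82 to 6.51 ± 1.19 CPM (SD, n = 5 each). Ncs1 itself fell by 0.51 (SE 0.04). For each of the 4 genes all 5 knockout libraries lay outside the wild-type range.

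These 4 genes, 2 higher and 2 lower, were the ones past an adjusted p of 0.05 among 14823 tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment. The adjusted p was 1.75e-05 for Ncs1 and Hmcn2, 0.00293 for Trub2 and 0.00295 for Lypd6b. At an unadjusted p under 0.05 there were 2199 genes, where 741 would be expected by chance. Genes that vary together can push such a number up or down, and cortex log2 fold changes went with exonic length across genes (r 0.22). The excess is therefore no count of changed genes. The count of genes past the adjusted threshold rested on 1 library. Without wild-type cortex replicate 5, 563 genes passed, 391 higher and 172 lower, the same 4 genes among them. DESeq2 called 169 genes in cortex. It shared Ncs1 and Trub2 with the 4 genes and gave Hmcn2 and Lypd6b no adjusted p. Their DESeq2 log2 fold changes were 3.12 and -1.05, with unadjusted DESeq2 p-values of 1.03e-30 and 6.07e-15. Trub2 overlaps Coq4 on the other strand, and the strand setting of the counting is not given in the sources used here, so reads of the pair could be shared. Coq4 was not called, with a log2 fold change of -0.00 (SE 0.09).

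The genes with the next smallest p in cortex did not pass. Thbs1, which encodes the matrix protein thrombospondin 1, had a log2 fold change of 0.98 (SE 0.16) and Pcdhb19, a clustered protocadherin, one of 0.45 (SE 0.07), both with an edgeR adjusted p of 0.0580. Pcdhb19 overlaps other gene models on its strand, which makes its counts uncertain. Cercam, which encodes an endothelial cell adhesion protein, had a log2 fold change of -1.04 (SE 0.17) and an edgeR adjusted p of 0.0719. Arl5a, Myoc, Zkscan16, Gm3558, Rev3l, Onecut2 and Golga7b followed, with edgeR adjusted p-values from 0.0794 to 0.113.

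**Figure D1:**
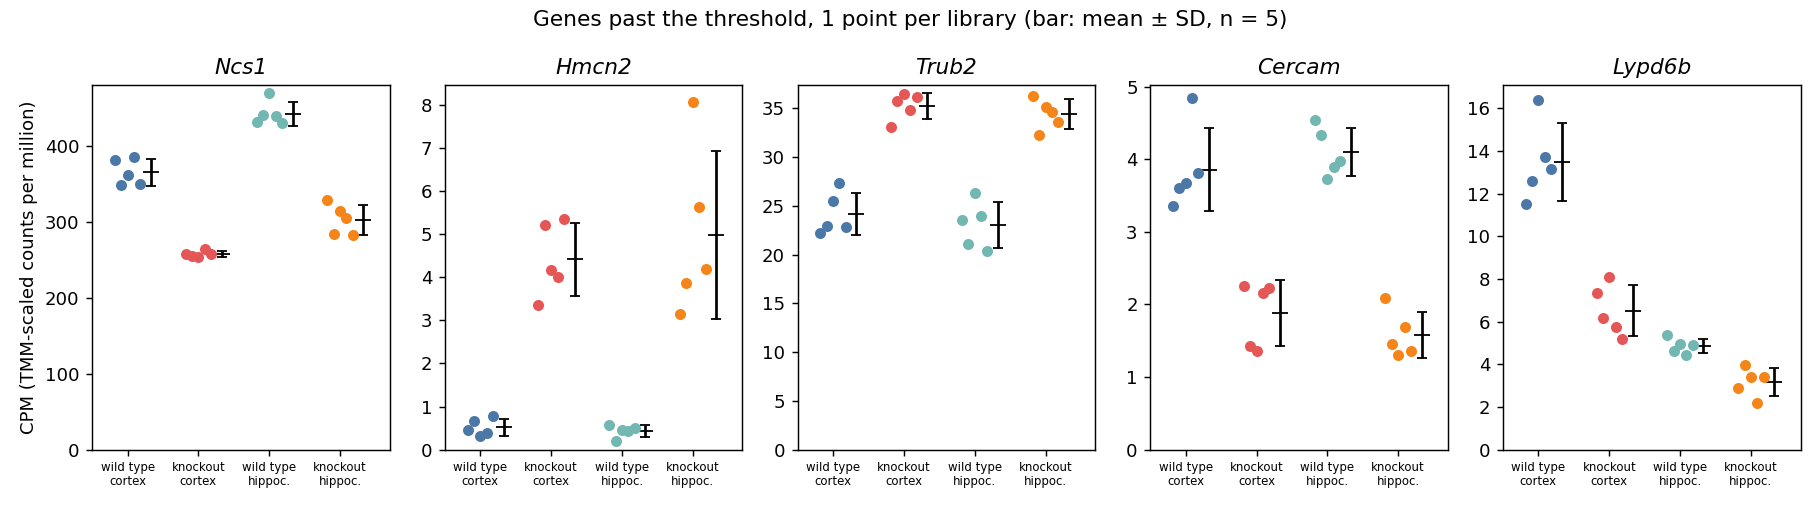
Levels of the 5 genes past the threshold in at least 1 region, in CPM on linear axes starting at 0, with 1 point per library and a bar for the mean ± SD (n = 5) of each group. Knockout libraries of cortex lie at 254 to 264 CPM for Ncs1, all below the wild-type libraries, and the groups also separate for Hmcn2, Trub2, Cercam and Lypd6b in both regions.

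Gene lists fixed before the data were examined were compared between genotypes in cortex. Nuclear genes of oxidative phosphorylation, which build the respiratory chain, lay lower in knockout for 59 of 59 members, with a median log2 fold change of -0.11. Of these, 14 passed when adjusted over the list alone and 0 when adjusted over all genes with edgeR, and 32 had an unadjusted p under 0.05. Their member with the smallest p was Cox7b, a subunit of cytochrome c oxidase, at a log2 fold change of -0.18 (SE 0.05). Ribosomal protein genes lay lower for 48 of 49 members, with a median of -0.09, and 0 passed when adjusted over the list alone. Interferon response genes lay higher for 20 of 22 members, with a median of 0.25, led by the antiviral gene Oasl2 at 0.81 (SE 0.23). Immediate early genes, which follow neuronal activity, lay higher for 20 of 25 members, with a median of 0.26, led by the transcription factor Klf4 at 0.58 (SE 0.20). In the interferon and immediate early lists 0 members passed when adjusted over the list alone. Camera with a preset correlation between genes gave an adjusted p of 8.82e-19 for oxidative phosphorylation, 1.34e-07 for ribosomal proteins, 0.000942 for the interferon response and 0.00498 for immediate early genes. With an estimated correlation the adjusted p was 0.512 for oxidative phosphorylation, 0.590 for ribosomal proteins and for the interferon response, and 0.751 for immediate early genes.

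Of 35 lists tested in cortex, 14 passed camera with the preset correlation, 6 higher and 8 lower, and 0 passed with an estimated correlation, where 0 also had an unadjusted p under 0.05. Fry called 0 lists for a shift in 1 direction and 1 list for change in either direction, the genes near Ncs1. Exact permutation tests of the library medians gave 4 lists with an unadjusted p under 0.05 and 0 after adjustment, the smallest adjusted p being 0.278. The other lists higher in knockout were circadian clock genes (median 0.16, 16 of 19 members), meningeal fibroblast markers (median 0.21, 14 of 15), striatal neuron markers (median 0.19, 16 of 16) and Y-linked genes (median 0.21, 4 of 4). Their preset adjusted p-values were 0.00382 for the clock and meningeal lists and 0.00656 for the striatal and Y-linked lists and the estimated ones were 0.590, 0.590, 0.702 and 0.512. Adjusted over the list alone, 2 Y-linked genes passed and 0 members of the other 3 lists. Their members with the smallest p were the clock repressor Per3 at 0.50 (SE 0.15), the collagen gene Col1a2 at 0.47 (SE 0.16), the signalling regulator Rgs9 at 0.48 (SE 0.21) and the demethylase gene Kdm5d at 0.24 (SE 0.07). The other lists lower in knockout were astrocyte markers (median -0.09, 13 of 14 members), microglia markers (median -0.09, 15 of 16), excitatory neuron markers (median -0.11, 9 of 12), synaptic vesicle release (median -0.04, 23 of 30), calmodulin and its targets (median -0.06, 18 of 26) and the unfolded protein response (median -0.04, 15 of 20). Their preset adjusted p-values lay between 0.00374 and 0.0366, and their estimated ones between 0.512 and 0.702. Adjusted over the list alone, 1 gene passed in each of the microglia, excitatory and unfolded protein lists. These were the complement gene C1qb at -0.22 (SE 0.06), the calmodulin-binding postsynaptic gene Nrgn at -0.25 (SE 0.06) and the chaperone gene Calr at -0.22 (SE 0.06). In the astrocyte, vesicle and calmodulin lists 0 passed, and the smallest p belonged to Acsbg1 at -0.16 (SE 0.05), Syn1 at -0.13 (SE 0.04) and Calm3 at -0.12 (SE 0.04). The mean of the unfolded protein response list was 0.0007, opposite in sign to its median.

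**Figure D2:**
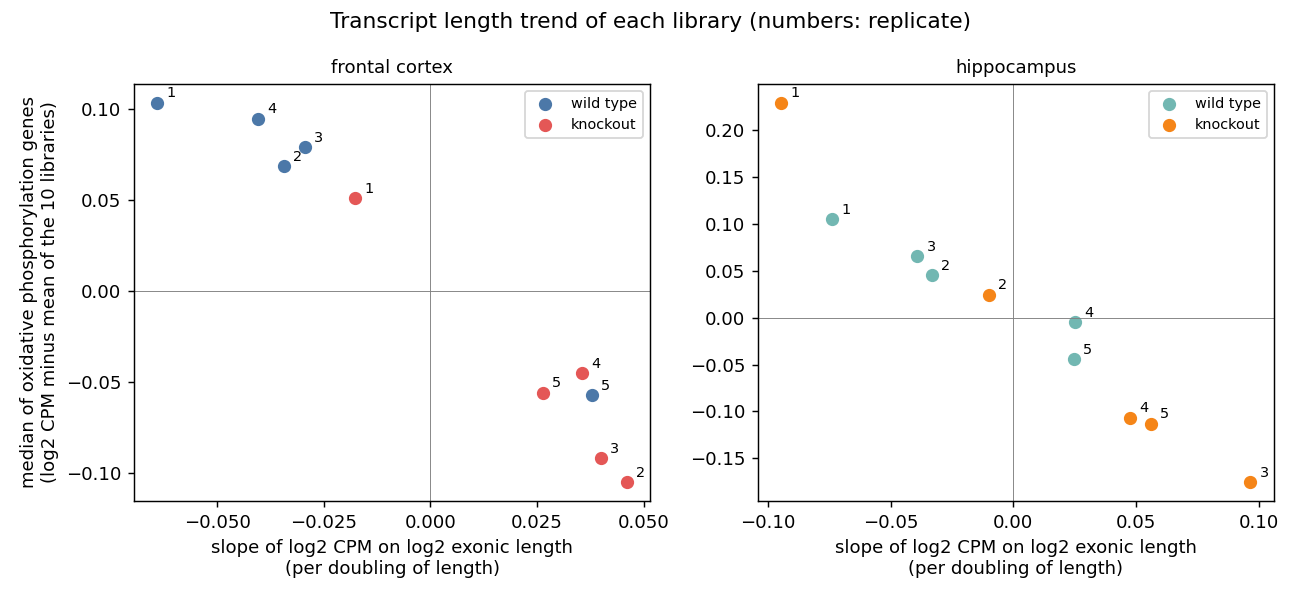
Median of the oxidative phosphorylation genes in each library (log2 CPM minus the mean of the 10 libraries of the region) against the slope of log2 CPM on log2 exonic length, with 1 numbered point per library and 1 panel per region. Wild-type cortex library 5 has a slope of 0.038 and lies among the knockout libraries, while the other wild-type cortex libraries have slopes from -0.064 to -0.029.

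The same question was asked in hippocampus. Hmcn2 rose from 0.432 ± 0.144 to 4.98 ± 1.95 CPM (SD, n = 5 each), a log2 fold change of 3.50 (SE 0.31) and an 11.3-fold difference. Cercam fell by 1.37 on the log2 scale (SE 0.15), from 4.10 ± 0.332 to 1.58 ± 0.317 CPM (SD, n = 5 each). Trub2 rose from 23.0 ± 2.39 to 34.4 ± 1.53 CPM (SD, n = 5 each), a log2 fold change of 0.58 (SE 0.07), and Ncs1 fell by 0.55 (SE 0.05). All 5 knockout libraries lay outside the wild-type range for each of the 4 genes.

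In hippocampus 4 of 15042 genes passed edgeR's quasi-likelihood test, 2 higher and 2 lower, with adjusted p-values of 0.00145 for Hmcn2 and Ncs1, 0.00337 for Cercam and 0.0121 for Trub2. At an unadjusted p under 0.05 there were 568 genes, where 752 would be expected by chance. Trub2 was not called when any 1 of wild-type replicate 2 or knockout replicates 1, 3 or 4 was left out, which left 3 genes. Lypd6b had a log2 fold change of -0.61 (SE 0.14) and did not pass, with an edgeR adjusted p of 0.991. Among the other genes with the smallest p were Myoc, at a log2 fold change of -0.74 (SE 0.14), Rbm43, at 0.61 (SE 0.12), and Xlr3b, a gene with near-identical copies and hence uncertain counts, at 2.09 (SE 0.43). Their edgeR adjusted p-values were 0.709, 0.809 and 0.887. Ccnyl1, 4933427I22Rik, Htra1, Dnah10, Gm15328 and C2cd5 had an edgeR adjusted p of 0.991.

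Astrocyte markers lay lower in knockout hippocampus for 11 of 14 members, with a median log2 fold change of -0.09. Camera gave them a preset adjusted p of 3.90e-05 and an estimated one of 0.202. Oxidative phosphorylation genes lay lower for 56 of 59 members, with a median of -0.06, a preset adjusted p of 4.84e-07 and an estimated one of 0.872. Calcium channels, pumps and stores lay higher for 29 of 37 members, with a median of 0.06, a preset adjusted p of 0.0305 and an estimated one of 0.872. The other lists past the preset threshold were lower, and each had an estimated adjusted p of 0.872. They were glucocorticoid response genes (median -0.11, 13 of 15 members), microglia markers (median -0.06, 12 of 16), ribosomal proteins (median -0.04, 36 of 49) and the unfolded protein response (median -0.05, 15 of 20, with a mean of 0.02). The neuronal calcium sensor family, to which Ncs1 belongs, did not pass, with medians of -0.07 in cortex and -0.02 in hippocampus and preset adjusted p-values of 0.114 and 0.336. Reported partners of NCS1 did not pass either, with medians of 0.06 and 0.02 and preset adjusted p-values of 0.294 and 0.959. In hippocampus 7 of 35 lists passed with the preset correlation, 1 higher and 6 lower, and 0 with an estimated one, where 1 had an unadjusted p under 0.05. Their members with the smallest p were Acsbg1 at -0.14 (SE 0.05), Sdhd at -0.11 (SE 0.05), Cacna1d at 0.30 (SE 0.11), Mt2 at -0.29 (SE 0.09), C1qc at -0.20 (SE 0.07), Rplp0 at -0.13 (SE 0.06) and Atf3 at 1.27 (SE 0.50). In each of these 7 lists 0 members passed when adjusted over the list alone.

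The labels put both regions in 1 design, so the difference between the genotype effects was tested. Hmcn2, Trub2, Cercam and Ncs1 had interaction p-values of 0.392, 0.769, 0.162 and 0.472 with edgeR. Lypd6b, called in cortex alone, had an interaction p of 0.0395 with edgeR and an adjusted p of 0.9998. No gene passed, 0 of 15310 with edgeR's quasi-likelihood test, with 214 at an unadjusted p under 0.05 where 766 would be expected, and limma-voom also called 0. DESeq2 called 1 gene, Serpina3g, a serine protease inhibitor induced by interferon, with an interaction log2 fold change of -3.06 and an adjusted p of 0.000516. Serpina3g had an edgeR adjusted p of 0.122, and of 0.00296 without knockout cortex replicate 5. Its level was low in cortex, at 0.04 to 0.17 CPM in wild type and 0.18 to 1.31 CPM in knockout. In hippocampus it was at 2.95 to 3.87 CPM in wild type and 2.80 to 3.66 CPM in knockout, so the difference lay in cortex.

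The called genes were then placed on the genome, in the coordinates of build mm10. Ncs1 lies on chromosome 2 from 31245923 to 31295471, and Hmcn2 starts 18.9 kb beyond it on the same strand, from 31314332 to 31460738. Trub2, from 29774684 to 29787671, lies 1.46 Mb away on the other side, and Cercam, from 29869494 to 29882840, lies 1.36 Mb away. Lypd6b, from 49787686 to 49948846, lies 18.5 Mb away. Within 10 Mb of Ncs1, 2 of 238 tested genes were called in cortex against 1 of 14584 elsewhere (Fisher's exact test, two-sided p 0.000762). In hippocampus 3 of 243 were called within 10 Mb and 0 of 14798 elsewhere (Fisher's exact test, two-sided p 4.17e-06), where edgeR, DESeq2 and limma-voom made 4, 6 and 4 calls over all genes.

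**Figure D3:**
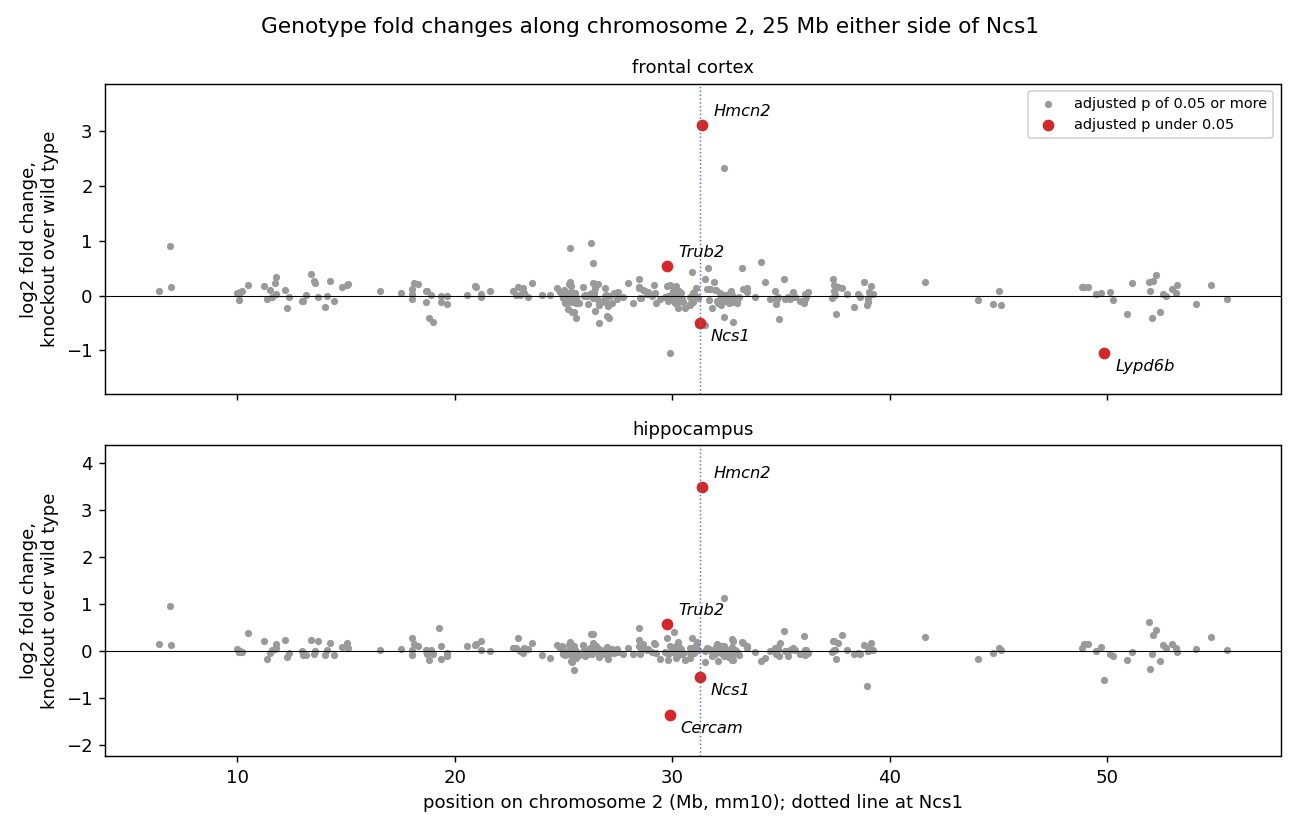
Genotype log2 fold change of each tested gene within 25 Mb of Ncs1 against its position on chromosome 2 in Mb, with 1 panel per region, red for an edgeR adjusted p under 0.05 and a dotted line at Ncs1. Hmcn2 stands at 3.11 in cortex and 3.50 in hippocampus.

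The regions were compared within each genotype. In wild type, Dsp, which encodes the junction protein desmoplakin found in dentate granule cells, was at 0.311 ± 0.162 CPM in cortex and 59.2 ± 23.8 CPM in hippocampus (SD, n = 5 each), a log2 fold change of 7.53 (SE 0.44). Slc9a4, a sodium-proton exchanger, Lhx9, a homeobox factor, C1ql2, a synaptic organizer of mossy fibres, Lct, Tspan18 and Il16 were higher in hippocampus, with log2 fold changes from 4.10 to 5.64. Ttr, the transthyretin of choroid plexus, had a log2 fold change of 9.49 (SE 2.26), and its level ranged from 4.85 to 1982 CPM between wild-type hippocampus libraries; limma-voom did not call it, with an adjusted p of 0.339. Adora2a, an adenosine receptor of striatal neurons, was higher in cortex, at 33.6 ± 5.20 against 1.45 ± 0.243 CPM (SD, n = 5 each), a log2 fold change of -4.52 (SE 0.15). Igfn1, Foxp2, Rasgef1c, Scn4b and the dopamine receptors Drd2 and Drd1 were also higher in cortex, with log2 fold changes from -4.21 to -3.38.

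In knockout, Dsp differed by 7.37 (SE 0.31) on the log2 scale, and Slc9a4, C1ql2, Lct, Lhx9, Fibcd1, Tspan18 and Cabp7 were higher in hippocampus, with log2 fold changes from 3.82 to 5.77. Igfn1, Adora2a, Rasgef1c, Foxp2, Drd1, Scn4b and Drd2 were higher in cortex, with log2 fold changes from -5.15 to -3.40. Cabp7 overlaps Zmat5 on the other strand and Ttr overlaps Gm16090 likewise, so their counts could include reads of the partner. With edgeR's quasi-likelihood test 5861 of 14849 genes differed in wild type, 2788 higher in hippocampus and 3073 lower, and 5838 of 15032 in knockout, 2891 higher and 2947 lower. Which side held more genes turned with total-count scaling, with 3168 higher and 2741 lower in wild type and 3375 higher and 2663 lower in knockout. It also turned with no filter, with 3022 higher and 2979 lower in wild type and 3118 higher and 2892 lower in knockout. In knockout it turned as well when cortex replicate 1, cortex replicate 4 or hippocampus replicate 1 was left out. Of 14784 genes tested in both, 4776 were called in both genotypes, all in the same direction, where independent lists would share 2282. Striatal neuron markers had a median of -2.82 in wild type and -3.03 in knockout, hippocampal subfield markers 2.33 and 2.23, cortical layer markers -1.44 in each, and choroid plexus and ependyma markers 2.45 and 2.73. Camera with an estimated correlation called 0 lists in wild type and 1 in knockout, hippocampal subfield markers, with an adjusted p of 0.0206. Each region was sequenced in its own lane, so region and lane cannot be told apart.

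**Figure D4:**
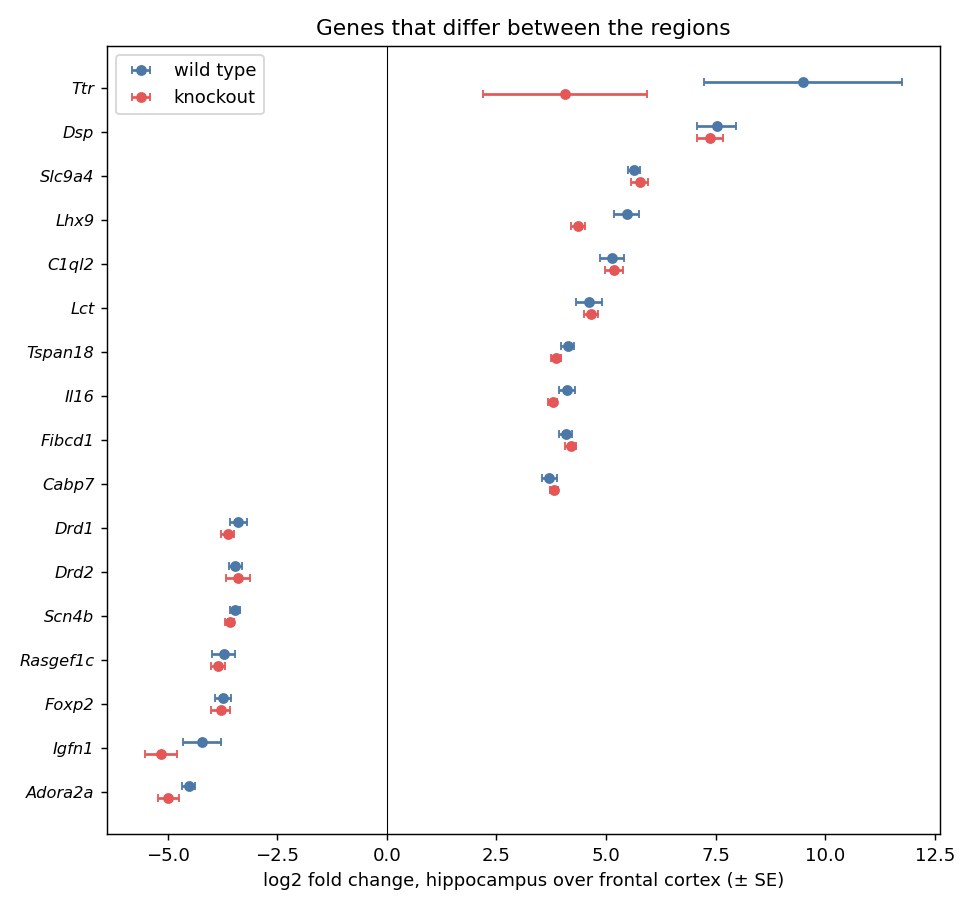
Log2 fold change of hippocampus over frontal cortex (± SE) for genes named for their large differences, with blue for wild type and red for knockout (n = 5 libraries per group). Dsp stands at 7.53 and 7.37, and Ttr has the widest error.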

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

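The tests below of the called genes of both regions together, of read-through and of a donor-strain stretch, of the length trend by list, of the share of neurons, of wild-type cortex library 5 and of shared numbers were chosen after the result was seen, and the counts over other splits before; the windows around Ncs1 in each region were set before the data were examined.

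Of 176 groups of 5 libraries checked for a library far from the others, 11 had one (6.25%), where Dixon's test marks about 1 in 20 groups by chance, here about 9. A gap as a share of the group's range measured the distance. In wild-type cortex it was 0.719 for synaptic vesicle release (library 3), 0.749 for monoamine receptors and metabolism (library 1) and 0.782 for oxidative phosphorylation (library 5). In knockout cortex it was 0.751 for the share of Rn45s (library 1, 4% against at most 1.79% in the others), 0.758 for neurotrophins and growth factors (library 4) and 0.769 for the unfolded protein response (library 4). In wild-type hippocampus it was 0.854 for glutamate receptors (library 1), 0.862 for choroid plexus and ependyma markers (library 4), 0.746 for striatal neuron markers (library 5) and 0.716 for Ncs1 (library 3, 470 CPM against at most 441). In knockout hippocampus it was 0.784 for genes near Ncs1 (library 1).

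The genotype effect of 6 lists differed between regions by camera with a preset correlation. The adjusted p was 0.000618 for oxidative phosphorylation, 0.000279 for the interferon response and for meningeal fibroblast markers, 0.00271 for the circadian clock, 0.0382 for the glucocorticoid response and 0.0273 for ribosomal proteins. With an estimated correlation 0 lists passed, the smallest adjusted p being 0.943, and 0 of 112 named genes had all libraries of the regions moving in opposite directions.

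Other splits of the libraries into groups of 5 were counted for each result, 100 splits per result with the real one included. As many genes as the real 4 came from 2 splits in cortex, where the highest other gave 6. In hippocampus 2 splits did so, and the highest other gave 4. This argues against chance for each count as a whole. Each count includes Ncs1, however, which the genotype grouping separates by design, so the splits do not weigh the other genes alone. For the regions 1 split gave as many, the real one, both in wild type (5861 genes, highest other 1) and in knockout (5838, highest other 0). A count of 0, as for the interaction, is reached by any split (here all 100, the highest giving 23), so the splits say nothing about chance there. The 14 lists of cortex were reached by 11 splits, the highest other giving 19, and the 7 lists of hippocampus by 80, the highest other giving 17, so chance cannot be excluded for either. The correlation of the genotype fold changes of the regions across genes, which are not independent replicates, was 0.464. It was reached by 5 of 126 splits made alike in both regions, with a highest other value of 0.608.

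The first pattern weighed was the place of the 4 called genes other than Ncs1. All lay within 20 Mb of Ncs1, as 305 of 15251 tested genes did (Fisher's exact p 1.57e-07). This argues against NCS1 loss acting on genes wherever they lie as the source of these 4 as a set. It does not decide for Lypd6b alone, which lies 18.5 Mb away, outside the 10 Mb window. Such an effect stays open for Lypd6b, and also for other genes, since most of the larger sets of calls lay elsewhere. With the genes that prompted the test left out, 15 of 548 genes called without wild-type cortex library 5 lay within 20 Mb. Among tested genes 295 of 14894 did (Fisher's exact p 0.208). That set is itself unsure, since 62 genes were called without this library once the length trend of each library was removed. Of the genes called by DESeq2, 7 of 162 lay within 20 Mb, a larger share than the 294 of 14802 tested (Fisher's exact p 0.0431). Read-through from Ncs1 cannot reach a gene before its start, and its reads would add to the counts of a gene beyond its end. This argues against it for 3 of the 4, since Trub2 and Cercam lie before the start and Lypd6b fell and lies 18.5 Mb away. For Hmcn2, 18.9 kb beyond Ncs1 on the same strand, it stays open, as does a local effect of the altered allele. A local effect was not tested for the other 3, which lie 1.36 Mb or more away. A candidate explanation that also stays open is a stretch of donor-strain chromosome around the targeted allele, whose strain is not given in the sources used here. With the genes that prompted the test left out, 10 of 236 genes 2 to 25 Mb away had a p under 0.01 in the same-numbered libraries added up, against 310 of 14556 on other chromosomes (Fisher's exact p 0.0384) and 26 of 913 farther along chromosome 2 (Fisher's exact p 0.294). The 3 genes left out at that distance were Lypd6b, Arl5a (21.1 Mb away) and Rbm43 (20.6 Mb away). With them the count was 13 of 239 (Fisher's exact p 0.00286 against other chromosomes), but they had prompted the test. Farther along the share was uneven, with 1 of 148 genes at 25 to 50 Mb and 26 of 766 beyond 50 Mb when no gene was left out.

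The second pattern was the lower level of oxidative phosphorylation and ribosomal protein genes in knockout cortex, which may follow from a trend with transcript length that differs between libraries. Random lists matched on length and expression had a median of -0.08 in place of the -0.11 of oxidative phosphorylation genes. The list lay at percentile 0.2 of 10000 of them (0.03 when matched on length alone), so its median was lower than unrelated genes of like length gave. Members of a list can vary together, which random lists do not allow for. The percentile therefore cannot decide whether length was the whole cause. With the length trend of each library removed, this list and the ribosomal proteins still passed camera in cortex with the preset correlation. Neither passed with an estimated correlation in the main fit, so this cannot decide it either. Microglia markers, weighed below, no longer passed once the trend was removed. Ribosomal protein genes lay at percentile 9.91 of lists matched on length and expression but at 2.1 of those matched on length alone, which leaves length open for them; the limit first set was joint, would have argued against length for both lists, and was divided by list after the percentiles were seen. A lower share of neurons would raise glial markers, yet microglia markers lay lower by list medians (-0.11, exact permutation p 0.0238, or 0.0714 adjusted over 3 glial lists), as did astrocyte markers (-0.09, exact permutation p 0.198), while oligodendrocyte markers lay higher (0.04, exact permutation p 0.532). The limit first set was on the unadjusted p and would have excluded this explanation; it was moved to the adjusted p after the value was seen, because 3 lists were tested, so a lower share of neurons stays open.

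The third pattern was the rise from 4 to 563 genes without wild-type cortex library 5. With the length trend of each library removed, 62 genes were called without it and 5 with it, so the trend may account for much of the rise but not for all of it. A wrong genotype label is argued against by Ncs1, at 349 CPM in this library against at most 264 CPM in knockout cortex, and by Hmcn2, at 0.773 CPM against at least 3.35 CPM. No biological explanation was tested. By the sample-sheet numbers in the labels, wild type came before knockout in each region. The number of this library was the last of wild-type cortex, next to that of knockout cortex library 5. Genotype and sample-sheet order therefore cannot be told apart, and whether that order bears on the length trend or on this rise was not tested.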

How the results depend on the processing

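The settings with the length trend or Rn45s removed, with 3 hippocampus libraries left out for their Ttr and with genotype and number taken as 1 mouse were chosen after the data were seen.

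In cortex the 4 genes remained called under RLE, upper-quartile and total-count scaling, limma-voom, both other filters and the replicate block. DESeq2 called 169 genes, 82 higher and 87 lower, 2 of them shared, and gave no adjusted p to 7759 genes. All 20 libraries in 1 fit gave 7, adding Cercam, Myoc and Serpina3g. Removing genes near Ncs1 left 2 in cortex and 1 in hippocampus by construction. Leaving out 1 library gave 4 to 563 genes in cortex, 563 without wild-type replicate 5 (69.45% higher, against 50%), and 3 to 4 in hippocampus. In hippocampus glmTreat against a 1.2-fold change kept 2, Hmcn2 and Cercam, and lost Ncs1 and Trub2; in cortex it lost Trub2. Without the 3 libraries with the most Ttr, 0 passed with edgeR. Fewer libraries remained, and the smallest adjusted p was 0.0955, for Hmcn2, whose log2 fold change was 3.52 and whose adjusted p under its 14 other settings was at most 0.0138. The log2 fold change of Ncs1 stayed between -0.52 and -0.49 in cortex and between -0.59 and -0.52 in hippocampus with 1 library left out.

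For the interaction DESeq2 called 1 gene, and leaving out 1 library gave 0 to 1. Between regions glmTreat against a 1.5-fold change, a stricter test, called 1131 genes in wild type (41.4% higher) and 1193 in knockout (41.6% higher). Leaving out 1 library gave 5352 to 5786 and 5122 to 5981.

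Camera with an estimated correlation and fry for a shift in 1 direction each called 0 lists in cortex and 0 in hippocampus; fry for change in either direction called 1 in each. Leaving out 1 library gave 8 to 18 lists in cortex, 8 without knockout replicate 1, and 4 to 11 in hippocampus, 4 without wild-type replicate 5 and 11 without wild-type replicate 1. With each library left out in turn, oxidative phosphorylation, ribosomal proteins, interferon, clock, microglia and Y-linked lists kept passing in cortex, and oxidative phosphorylation and astrocyte lists in hippocampus; the other lists were lost without at least 1 library. With the length trend removed 4 lists passed in hippocampus, 3 of them shared; calcium channels, ribosomal proteins, the unfolded protein response and microglia were lost. In cortex 12 of the 14 were kept, and microglia and the unfolded protein response were lost. The cause of these shifts was not tested unless stated.

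The replicate block gave 4 genes in cortex and 4 in hippocampus, 0 for the interaction, 6629 and 6250 between regions in wild type and knockout, and 15 and 8 lists. The 4 genes of each region were the same ones. Same-numbered libraries deviated together by correlations across genes from -0.06 to 0.14 between genotypes in cortex and from -0.00 to 0.30 in hippocampus. Between regions the range was 0.08 to 0.37 in wild type, where each of the 5 libraries matched its own number best, and -0.14 to 0.19 in knockout. The main fits did not take the numbers as pairs, because the labels do not say what a number marks. That choice was made before the data were examined and does not rest on these correlations. The fit of the interaction with genotype and number as 1 mouse called 0 genes with edgeR, with 325 at an unadjusted p under 0.05 where 766 would be expected, and the replicate block gives the paired count between regions.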

Other observations

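The tests of shared numbers were chosen after the result was seen.

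Immediate early genes varied together in the regions by number. Over 10 same-numbered pairs the list medians of cortex and hippocampus had a Pearson r of 0.899 (one-sided permutation p 0.00115) and a Spearman rho of 0.867 (one-sided permutation p 0.00329), and r was 0.803 without the 2 pairs farthest from the median. Other genes of same-numbered libraries had a mean correlation of 0.132 (one-sided permutation p 0.00361). These values raise the hypothesis that same-numbered libraries of a genotype came from the same mouse, which the labels do not state. The hint was weaker in knockout. Between regions, same-numbered libraries had a mean correlation across genes of 0.187 in wild type and 0.0835 in knockout. Knockout cortex libraries 1 and 2 did not match their own number best. A handling order shared by the same number in both genotypes would cancel in wild type minus knockout by number, yet this difference of the list medians still went together between regions over 5 numbers (r 0.942, one-sided exact permutation p 0.0167). That argues against such an order as the whole cause. It cannot weigh the order of the sample-sheet numbers, which ran nearly alike in both regions with wild type first. An effect of that order would not cancel in wild type minus knockout, so it stays open beside the same mouse.

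Ttr, the transthyretin of choroid plexus, was at 2014 CPM in wild-type hippocampus library 4, 3162 CPM in knockout hippocampus library 2, 324 CPM in knockout hippocampus library 4 and 206 CPM in knockout cortex library 1. In the other hippocampus libraries it was between 2.98 and 28.9 CPM.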
